A study of Homo sapiens with 6 samples.

How the data were processed

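RNA of 6 libraries of LNCaP-AI cells, 3 with a control vector and 3 with a hairpin against hsa_circ_0092339, was sequenced by the submitters. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made by a standard Illumina procedure; whether ribosomal RNA was removed or polyadenylated RNA selected is not given in the sources used here. The submitters' processing notes name cutadapt, HISAT2 and StringTie, without versions, and the genome build hg18. The coordinates in the tables are nevertheless those of GRCh38: all 99 genes of the gene FPKM table overlap the place of the same gene in GENCODE 29 on GRCh38, and 95 of the 99 isoforms have the same start and end.

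Per the file headers, the authors deposited FPKM values, which are fragments scaled for feature length and for the mapped fragments of the library, and counts side by side for genes and for isoforms, and 2 further tables of whole-number counts per gene and per transcript. Each table was analysed for 99 rows. Among the analysed rows, 0 genes are in both gene tables and 0 transcripts are in both transcript tables. Features with a count of 0 are listed at an FPKM of 0.0001 in the authors' tables. For 76 genes with a mean of at least 100 counts, the deposited count divided by FPKM and depth varied between libraries by at most 2.39%, so the 2 units of that table are the same measurement on different scales. The deposited isoform length, a value of another kind, was used only to recover the depth. Gene symbols of the count table came from a table of gene names, in which 98 of its 99 identifiers were found, and 88 of 99 transcripts were found in GENCODE 29.

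The number of mapped fragments per library was recovered from the isoform table from the count, the length and the FPKM, as the median over 23 or 24 isoforms with at least 1000 counts. It was 58091756, 58606592 and 68990788 in the control libraries and 53127020, 80559726 and 73620788 in the knockdown libraries. These totals were used as library sizes, except by DESeq2, because the sum of 99 rows is not the depth of a library. DESeq2 took its size factors from the tested rows, so it differs from edgeR in scaling too. Low features such as MISP3 and several mitochondrial tRNAs rest on fewer counts and are less precise than FKBP4 or MT-RNR2.

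Before replicates were averaged they were compared by a chi-square statistic of the counts over 115 or 116 genes. It was 26.9 to 70.9 per degree of freedom over the 6 pairs within a group, far above counting noise, so no pair was taken for a repeated deposit of 1 library.

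Counts were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors on the tested rows, filterByExpr by group, R 4.3.3). FPKM values were tested with limma 3.58.1 (trend) on log2(FPKM + 1), for rows with a mean of at least 1 FPKM. Calls have a Benjamini-Hochberg adjusted p under 0.05, adjusted only over the tested rows of a table, and a fold change is knockdown over control. Shares of fragments were compared with an exact two-sided permutation test, which with 3 against 3 cannot go below 0.1. DESeq2 1.42.0, limma-voom, other scalings, filters and pseudocounts, a replicate block and leaving out each library were the alternatives, whose effect is given in the closing section. The designs, gene lists and most alternatives were fixed before the data were examined; 5 alternatives were added afterwards.

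The rule for named genes took the 10 largest called rises and falls with a symbol, a mean of at least 50 counts or 5 FPKM and groups that do not overlap, plus a few genes fixed beforehand, among them MYC, KLK3, KLK2, TMPRSS2, FKBP5 and CDKN1A, and up to 4 called members of each gene list. With fewer than 20 such genes it took all called genes with a symbol, which was the case (16 in the FPKM table and 3 in the count table met the rule). From the isoform table it took the 3 largest called rises and falls. The other called isoforms, and PLCXD1, GTPBP6, SLC7A2, SEPTIN5 and MRPL49, were named after their values were seen.

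The tests were tried on simulated counts drawn from the real means, depths and dispersions, with a seeded part of the rows changed, in 20 draws per table. At 2-fold, 92.8% of changed genes were called in the gene FPKM table (about 69.7 tested), 47.1% in the gene count table (29.9 tested), 30.3% in the isoform FPKM table (44.7 tested) and 2.63% in the transcript count table (24.6 tested). At 1.3-fold the shares were 26.0%, 6.52%, 1.59% and 0%, and at 8-fold 100%, 96.9%, 100% and 20%. Of unchanged rows 0.801%, 0.617%, 0.139% and 0% were called, in the same order of tables. Reads of mitochondrial transcripts can also match nuclear copies of the mitochondrial genome, and how multiply mapped reads were counted is not given in the sources used here.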

Results

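RNA was sequenced from LNCaP-AI cells, a castration-resistant line derived from the androgen-responsive LNCaP prostate cancer line. The cells carried either a control vector (3 libraries) or a short hairpin construct against the circular RNA hsa_circ_0092339 (3 libraries, called knockdown here). The series names a sponge mechanism that links this circular RNA to the microRNA hsa-mir-940 and to MYC. The comparison asks which transcripts differed between cells with the hairpin and cells with the control vector. The labels give all 3 knockdown libraries the same hairpin name. Effects of the hairpin on other RNAs thus cannot be told apart from effects through the circular RNA. By the scaling of the deposited FPKM values, the control libraries held 58091756, 58606592 and 68990788 mapped fragments and the knockdown libraries 53127020, 80559726 and 73620788. Values of 4 kinds were analysed, each for 99 rows: FPKM per gene, FPKM per isoform, counts per gene and counts per transcript. These rows are only a part of each table, and among them no gene or transcript was shared between FPKM and count rows. The genes analysed from the gene FPKM table have identifiers from ENSG00000000003 to ENSG00000005469 and are not a random draw. Shares of called rows therefore hold for the analysed rows only. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

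The targeted circular RNA was not analysed here, because no row carried its identifier, and the knockdown itself was therefore not checked. MYC, KLK3, KLK2, TMPRSS2, FKBP5 and CDKN1A, which were fixed beforehand as genes to report, were likewise not analysed here.

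Among the 70 analysed genes of the gene FPKM table with a mean of at least 1 FPKM, 14 rose and 8 fell in the knockdown libraries. FKBP4, which encodes an HSP90 co-chaperone of steroid receptors, rose from 54.2 ± 0.307 FPKM in the controls to 75.7 ± 1.98 FPKM in the knockdown (mean ± SD, n = 3 each), a ratio of 1.40. HCCS, the enzyme that attaches heme to mitochondrial cytochromes c, had the largest log2 rise among the called genes, rising from 17.0 ± 0.775 to 24.8 ± 1.58 FPKM. ICA1, a protein of the secretory pathway, had the largest fall among them, from 3.56 ± 0.246 to 1.81 ± 0.335 FPKM, and SEMA3F, a secreted semaphorin, fell from 3.09 ± 0.272 to 1.88 ± 0.159 FPKM. The changes were moderate in size: the ratio of the group means ran from 1.16 to 1.46 over the genes that rose and from 0.507 to 0.874 over those that fell.

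**Figure D1:**
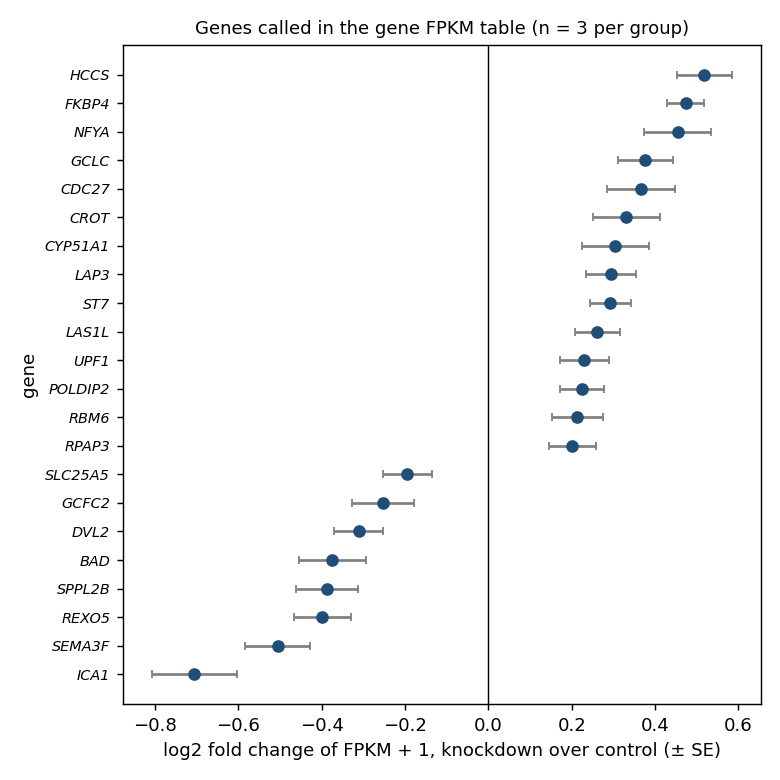
Fitted log2 fold change of FPKM + 1 (horizontal axis, knockdown over control) of the 22 called genes of the gene FPKM table (vertical axis); points are estimates and bars are standard errors, with 3 libraries per group. The 14 genes that rose lie between 0.20 and 0.52, and the 8 that fell between -0.71 and -0.19; with quantile normalization UPF1 lay at -0.035 and was not called.

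GCLC, the catalytic subunit of the first enzyme of glutathione synthesis, rose from 4.11 ± 0.368 to 5.62 ± 0.142 FPKM. CROT, a peroxisomal carnitine acyltransferase, rose from 2.01 ± 0.123 to 2.80 ± 0.328 FPKM, and LAP3, a cytosolic leucine aminopeptidase, rose from 19.3 ± 1.13 to 23.9 ± 0.792 FPKM. SLC25A5, an ADP/ATP carrier of the inner mitochondrial membrane, fell from 340 ± 15.7 to 297 ± 18.2 FPKM; it has close paralogs and processed copies in the genome, so its value is uncertain where reads could be shared.

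NFYA, a subunit of the CCAAT-binding factor NF-Y, rose from 11.8 ± 0.742 to 16.6 ± 1.57 FPKM. CDC27, a subunit of the anaphase-promoting complex, rose from 14.1 ± 1.36 to 18.5 ± 1.11 FPKM, and LAS1L, which takes part in processing of ribosomal RNA, rose from 22.8 ± 1.03 to 27.5 ± 0.706 FPKM. UPF1, the helicase of nonsense-mediated decay, went from 17.6 ± 0.519 to 20.9 ± 1.26 FPKM, RBM6 from 8.88 ± 0.367 to 10.5 ± 0.666, RPAP3 from 10.5 ± 0.580 to 12.2 ± 0.353 and POLDIP2 from 38.2 ± 1.36 to 44.8 ± 1.41. REXO5, an RNA exonuclease, fell from 4.12 ± 0.233 to 2.89 ± 0.254 FPKM, and GCFC2 fell from 7.88 ± 0.780 to 6.43 ± 0.255. DVL2, a Wnt pathway adaptor, fell from 14.1 ± 0.470 to 11.1 ± 0.621 FPKM, and SPPL2B, an intramembrane protease, fell from 4.09 ± 0.348 to 2.89 ± 0.223. ST7 rose from 3.26 ± 0.0986 to 4.22 ± 0.110 FPKM.

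In the limma fit on log2(FPKM + 1), a scale that understates the change of low genes, the log2 fold change was 0.47 ± 0.0444 (SE) for FKBP4 (adjusted p = 0.00149), 0.52 ± 0.0654 for HCCS (adjusted p = 0.00462), -0.71 ± 0.102 for ICA1 (adjusted p = 0.00681) and -0.51 ± 0.0774 for SEMA3F (adjusted p = 0.00726). The 6 libraries split by group without overlap for all 22 called genes, but the calls rest on the same values, so this adds no evidence. Among the 70 tested genes 37 had groups that did not overlap, where chance gives 10% for a single gene. The genes come from the same 6 libraries and are not independent, so this share is only a description. ICA1, SEMA3F, ST7, REXO5, GCLC, NFYA and DVL2 kept their call under every alternative run, while 13 genes were called without knockdown 1, 14 without knockdown 3, and SLC25A5, GCFC2, RBM6 and RPAP3 lost the call under 10, 8, 7 and 7 of 14 alternatives. RBM6 and RPAP3 were each not called by limma without control 1, control 2, knockdown 1 or knockdown 3 (adjusted p up to 0.110, and from 0.0231 and 0.0245 over their alternatives). UPF1 was not called under 6 of 14, with quantile normalization and 5 others. POLDIP2 was not called under 4 of 14 (quantile normalization, replicate block, without control 1, without knockdown 3; limma adjusted p from 0.0124 to 0.290 over all alternatives). CROT was not called without control 3 or knockdown 1, and LAS1L without control 1 (limma adjusted p from 0.0131 to 0.0635 and from 0.0117 to 0.0510). With median centring 23 genes rose and 7 fell, and with quantile normalization 8 rose and 8 fell, 13 of them among the 22, without FKBP4 (limma adjusted p = 0.144, the highest over its alternatives, which began at 0.000712). HCCS (0.317 on the log2 scale), LAP3 (0.0980), SPPL2B (-0.338) and CDC27 (0.171) were not called with quantile normalization either, and CDC27 also not without knockdown 1. Over their alternatives the limma adjusted p ran from 0.00124 to 0.0527 for HCCS, from 0.0114 to 0.206 for LAP3 and CDC27, and from 0.0104 to 0.0527 for SPPL2B.

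FKBP4 lies at 2794970 to 2805423 on chromosome 12, HCCS at 11111301 to 11123086 on chromosome X, ICA1 at 8113184 to 8262612 on chromosome 7 and SEMA3F at 50155045 to 50189075 on chromosome 3, in the coordinates of the table, which match GRCh38. All 4 are annotated as protein-coding genes. Another annotated gene overlapped 17 of the 22 called genes, on the opposite strand for 16, and since the use of strand in counting is not given in the sources used here, such reads cannot be assigned with certainty. Most tested genes that were not called had such an overlap as well, so it was not particular to the called genes.

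Of the 34 gene lists fixed before the data were examined, 5 had a member in the gene tables, none had more than 2, and the 5 members needed for a set test were not reached, so none was run. In the list of MYC targets the 1 member was CCT3, a subunit of the TRiC chaperonin, which rose; in the list of cholesterol synthesis the 1 member was CYP51A1, the lanosterol demethylase, which rose from 31.0 ± 0.485 to 38.7 ± 4.01 FPKM. In the apoptosis list 1 of 2 members was tested: BAD, a pro-apoptotic BCL2 family member, fell from 15.0 ± 1.22 to 11.3 ± 0.884 FPKM. Each of these 3 lists had 1 tested member, so adjusting over the list alone left its p-value unadjusted. The call it kept there was fixed in advance and adds no evidence. PDK4, the 1 member of the PI3K and FOXO list, was not called in either way, and the 1 histone, H1-4, was too low to be tested. CCT3 was not called under 7 of 14 alternatives (adjusted p from 0.0113 to 0.421 over all of them): with DESeq2 (0.291), no low-count filter (0.415) and upper-quartile scaling (0.3525), and by edgeR without control 1 (0.421), control 2 (0.274), knockdown 2 (0.0864) or knockdown 3 (0.0570). CYP51A1 was not called under 5 of 14: by limma with quantile normalization (adjusted p = 0.0683) and without control 1 (0.0709), control 2 (0.0823), knockdown 1 (0.0859) or knockdown 3 (0.0950). BAD was not called without knockdown 1 (0.0527) or knockdown 3 (0.0520). Over all alternatives the p-values of CYP51A1 and BAD ran from 0.0128 to 0.0950 and from 0.0112 to 0.0527. The marker lists of other cell types and of luminal cells had no member in these tables.

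**Figure D2:**
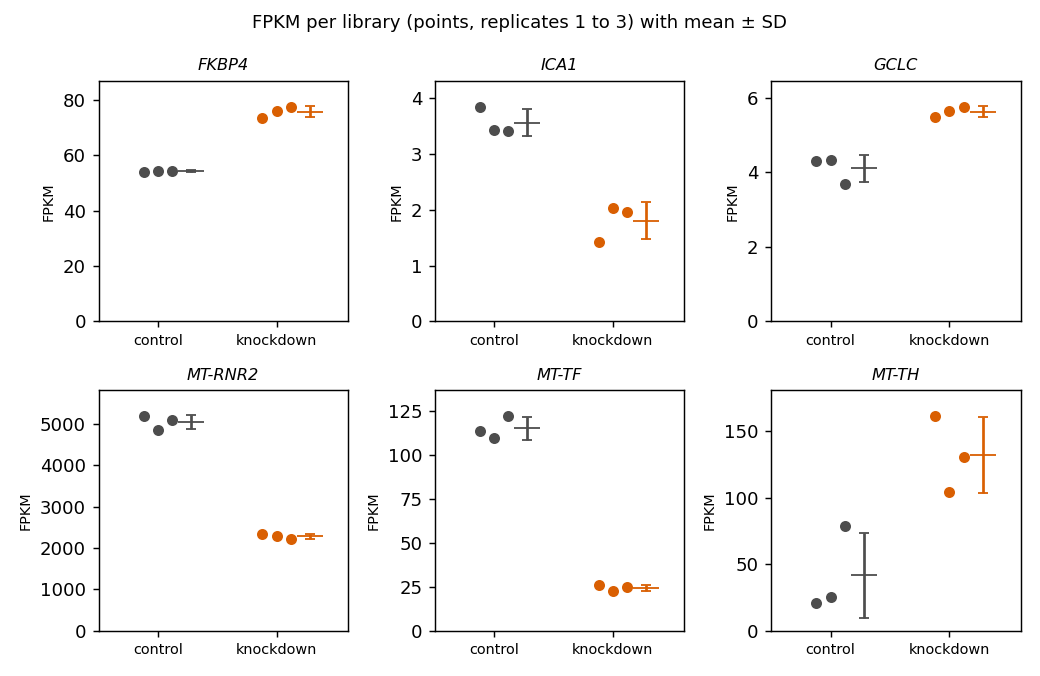
FPKM per library (vertical axis, from 0) for 3 genes and 3 mitochondrial transcripts in the control and knockdown groups; points are the 3 replicates, and the bar beside them is the mean ± SD. For MT-TH, control 3 (78.7 FPKM) lies between the other controls (21.1 and 25.6) and the knockdown libraries (104.8 to 161.5).

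In the gene count table, 31 of 99 genes had enough counts to be tested, and 1 rose and 3 fell. CCT3 rose from 479.8 ± 10.7 to 597.4 ± 33.5 CPM (counts scaled to mapped fragments). ATP6V1E2, a subunit of the vacuolar proton pump, fell from 6.84 ± 0.495 to 3.76 ± 0.194 CPM, and MISP3 fell from 2.70 ± 1.06 to 1.245 ± 0.119 CPM. The fourth, ENSG00000250568, has no symbol and was named only after its values were seen; it is annotated as a processed pseudogene inside PDS5A on chromosome 4 (39973128 to 39973442), so its reads are uncertain, and it fell from 1.39 ± 0.220 to 0.639 ± 0.200 CPM. By edgeR's quasi-likelihood test the log2 fold changes were 0.31 ± 0.0671 (SE) for CCT3 (adjusted p = 0.0273), -0.87 ± 0.164 for ATP6V1E2 (adjusted p = 0.0210) and -1.09 ± 0.260 for MISP3 (adjusted p = 0.0286). No gene was called without control 2 or without knockdown 3 (edgeR; 5 at an unadjusted p under 0.05 each time), 1 without knockdown 1 and 2 without control 1, and DESeq2 called 2 of the 4 on all libraries. MISP3 was not called under 9 of 14 alternatives (adjusted p from 0.0229 to 0.252 over all of them): with library size only, no low-count filter, limma-voom and upper-quartile scaling, and by edgeR without control 1, control 2, knockdown 1, knockdown 2 or knockdown 3. ATP6V1E2 was not called under 4 of 14 and ENSG00000250568 under 12 of 13. In GENCODE 29, CCT3 lies on chromosome 1 (156308968 to 156367873) and overlaps TSACC on the other strand, and ATP6V1E2 on chromosome 2 (46490750 to 46542557) overlaps RHOQ on the other strand.

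The analysed rows of the isoform FPKM table were the 37 transcripts of the mitochondrial genome and 62 transcripts of the pseudoautosomal end of the X chromosome. The values of the mitochondrial ribosomal RNAs fell, and whether ribosomal RNA was removed before sequencing is not given in the sources used here. MT-RNR2, the 16S rRNA, went from 5044 ± 170 to 2281 ± 66.6 FPKM, and MT-RNR1, the 12S rRNA, from 862 ± 36.8 to 575 ± 22.4 FPKM. The 3 tRNAs that flank them fell too: MT-TF from 115 ± 6.38 to 24.5 ± 1.78 FPKM, MT-TV from 30.6 ± 3.77 to 11.6 ± 0.617 and MT-TL1 from 1083 ± 94.0 to 756 ± 46.5. These 5 adjoining transcripts cover bases 577 to 3304 of the mitochondrial genome; with quantile normalization of the 45 tested isoforms MT-RNR1 and MT-TL1 had a change of 0, and the other 3 still fell.

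**Figure D3:**
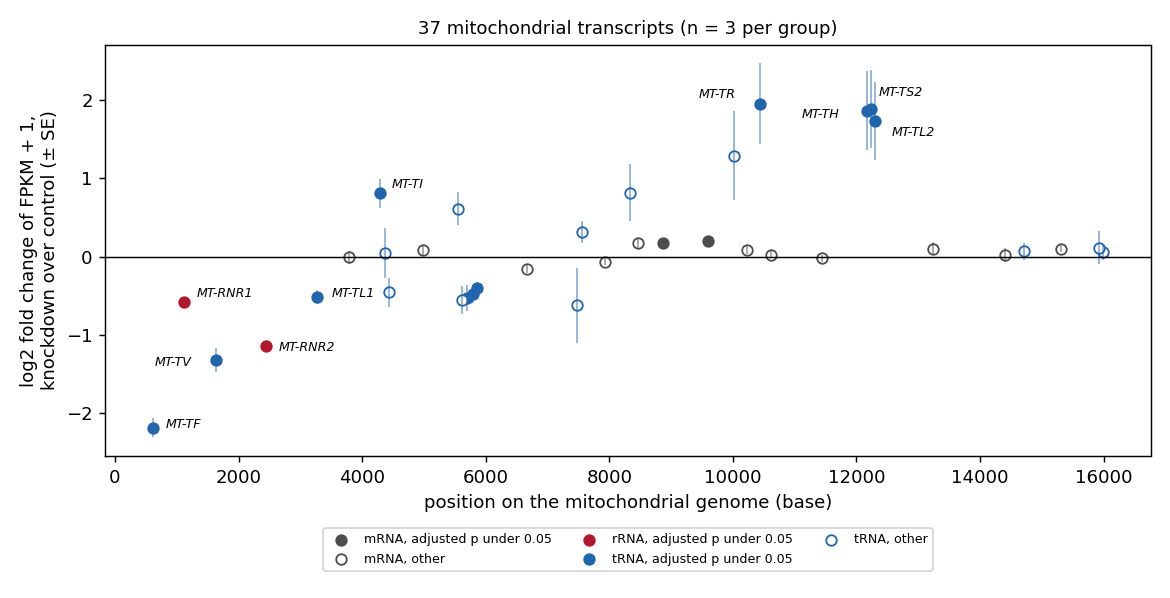
Fitted log2 fold change of FPKM + 1 (vertical axis, knockdown over control, bars are standard errors, 3 libraries per group) of the 37 mitochondrial transcripts against their position in bases (horizontal axis); filled points were called. The 5 transcripts from MT-TF to MT-TL1 lie between -2.19 and -0.52, although MT-RNR1 and MT-TL1 lay at 0 with quantile normalization, and the 13 mRNAs lie between -0.16 and 0.20.

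The mRNAs of the same genome moved little. Of the 13 mitochondrial mRNAs, 2 rose (MT-CO3 from 7060 ± 354 to 8128 ± 314 FPKM, and MT-ATP6 from 9452 ± 541 to 10610 ± 274), none fell, and 11 did not pass the test; scaled to the summed mitochondrial mRNAs, 3 rose and 3 fell. Neither rise was firm: MT-ATP6 was not called under 9 of 12 alternatives (limma, or edgeR on counts; adjusted p from 0.00266 to 0.648 over all of them) and MT-CO3 under 7 (0.0256 to 0.648). Without control 2, control 3, knockdown 1, knockdown 2 or knockdown 3 limma called neither, with adjusted p of 0.0721, 0.0604, 0.114, 0.0597 and 0.0709 for MT-CO3 and 0.0866, 0.0735, 0.132, 0.117 and 0.0709 for MT-ATP6. Among the 15 mitochondrial rRNAs and mRNAs fixed as a list, 2 rose, 2 fell and 11 did not pass, and 3 were called when adjusted over the list alone. The share of all fragments on the 37 genes was 8.18 ± 0.366% in the controls and 7.81 ± 0.268% in the knockdown (n = 3 each, exact two-sided permutation p = 0.3). The share on the rRNAs was 0.869 ± 0.0269% and 0.410 ± 0.00829% (exact p = 0.1, the smallest that 3 against 3 allow), and the share on the mRNAs was 7.26 ± 0.342% and 7.35 ± 0.260% (exact p = 0.9).

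Of the 19 mitochondrial tRNAs outside bases 577 to 3304, 5 rose, 3 fell and 11 were not called. MT-TY, MT-TC and MT-TN, neighbours on the minus strand between bases 5657 and 5891, fell, with ratios of 0.757, 0.721 and 0.701. None of the 3 was called without control 1, control 2 or knockdown 3; with quantile normalization MT-TC had a change of 0 and MT-TY was at 0.036 on the log2 scale. In all they were not called under 4, 4 and 8 of 12 alternatives. MT-TA, beside MT-TN on the same strand, had a ratio of 0.689 and was not called (limma adjusted p = 0.0535). MT-TR, MT-TS2 and MT-TH rose, with ratios of 3.48, 3.38 and 3.17, and MT-TL2 and MT-TI rose with ratios of 3.50 and 1.76. The size of the first 4 depended on control 3: without it the ratios of MT-TR, MT-TS2, MT-TH and MT-TL2 were 6.33, 5.79, 5.67 and 4.99, and without control 1 they were 2.86, 2.78, 2.54 and 2.96. The 3 tRNAs from MT-TH to MT-TL2 adjoin each other between bases 12138 and 12336. Of the plus-strand tRNAs that were not called, MT-TG (ratio 2.66), MT-TK (1.77), MT-TW (1.65), MT-TD (1.26) and MT-TT (1.075) were higher and MT-TM (0.728) was lower. On the minus strand MT-TE, MT-TP, MT-TQ and MT-TS1 were not called either, with ratios of 1.047, 1.039, 0.981 and 0.664. In control 3 the values of MT-TR, MT-TS2 and MT-TH were 41.0, 62.0 and 78.7 FPKM, against 11.6 to 25.6 in the other controls and 59.7 to 161.5 in the knockdown libraries. In total 7 isoforms rose and 9 fell of the 45 tested; outside the mitochondrial genome the call was the PPP2R3B isoform ENST00000390665, a regulatory subunit of protein phosphatase 2A on chromosome X (333933 to 386907), which fell from 8.88 ± 1.19 to 4.69 ± 0.362 FPKM. It was not called under 4 of 12 alternatives: by limma with quantile normalization (adjusted p = 0.191) and without control 1 (0.0659), knockdown 1 (0.0550) or knockdown 3 (0.0709); over all of them adjusted p ran from 0.00541 to 0.191.

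By limma the log2 fold change was -1.14 ± 0.0459 (SE) for MT-RNR2 (adjusted p = 1.23e-05), -2.19 ± 0.124 for MT-TF (adjusted p = 4.72e-05), -0.58 ± 0.0682 for MT-RNR1 (adjusted p = 0.0016) and 1.86 ± 0.504 for MT-TH (adjusted p = 0.0351). MT-RNR2, MT-TF and MT-TV were called under all 12 alternatives. None of the 5 tRNA rises was called without control 1, control 2, knockdown 1 or knockdown 3, or with quantile normalization. Of the 5, 1 was called with no low-value filter, 1 with edgeR on counts and 3 with the replicate block (not MT-TR or MT-TL2). Without control 1, control 2, knockdown 1 or knockdown 3, 7, 6, 7 and 5 isoforms were called in all.

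In the transcript count table no transcript of the 27 tested was called by edgeR's quasi-likelihood test, and 1 had an unadjusted p under 0.05. DESeq2 called 1 and limma-voom 0, with 3 and 5 at an unadjusted p under 0.05. In data simulated from these libraries the same test called 2.63% of transcripts changed 2-fold and 20% of those changed 8-fold. Taken over all tested transcripts, changes of that size were thus mostly not detectable. The standard error of the log2 fold change was 0.107 for RBM12B and 0.142 for LRFN1, against 1.27 for RIOX2 and 1.85 for PJVK. The simulated shares are therefore averages and do not hold for each transcript.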

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

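The alternatives chosen after seeing the data were the joint fit of both gene tables, edgeR on the counts of the FPKM tables, the scaling to mitochondrial mRNA, and limma-voom for transcripts. For the 34 named genes and isoforms, 334 of 451 alternative values kept the direction and the call, 116 kept the direction (or lay at 0) without the call, and 1 reversed: UPF1 with quantile normalization, at -0.035 on the log2 scale, and the cause was not tested. Among the other called rows MT-TY alone reversed, also with quantile normalization. Of the 22 named genes of the FPKM table, 7 kept the call under all alternatives run and 4 lost it only with quantile normalization.

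In the gene count table, 4 genes were called. The count was 2 with DESeq2, 2 with library size only, 2 with limma-voom, 1 with upper-quartile scaling and 2 with a fold change of at least 2. It was 0 with no low-count filter (edgeR, 49 genes tested, 6 at an unadjusted p under 0.05). Apart from the fold threshold, which removes small changes by construction, the cause was not tested. Leaving out 1 library gave 0 to 3 genes: 2 without control 1, 0 without control 2, 1 without knockdown 1 and 0 without knockdown 3. For transcripts DESeq2 called 1 where edgeR called 0 (1 at an unadjusted p under 0.05), and leaving out 1 library gave 0 to 1, with 1 call without knockdown 2 and 1 without knockdown 3; the cause was not tested.

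For the gene FPKM table (22 genes), leaving out 1 library gave 13 to 25 genes, with 13 without knockdown 1 and 14 without knockdown 3, all of them among the 22. For the isoform FPKM table (16 isoforms) the count was 9 with no low-value filter, where 68 isoforms were tested, 5 with quantile normalization and 10 with edgeR on counts (2 rises and 8 falls); the cause was not tested. Quantile normalization keeps only ranks, so a transcript whose rank is the same in every library has a change of 0. Leaving out 1 library gave 5 to 16 isoforms: 7 without control 1, 6 without control 2, 7 without knockdown 1 and 5 without knockdown 3.

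The libraries share only replicate numbers: deviations of same-numbered libraries from their group means had correlations of -0.257, 0.195 and 0.0671 over 101 genes, so not every library correlated best with its own number. With the replicate block 3 genes of the count table, 17 of the FPKM table, 0 transcripts (edgeR, 0 at an unadjusted p under 0.05) and 15 isoforms were called.

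The FPKM fit on genes of both tables gave no value, since no analysed gene is in both. The settings for MYC and for the gene list tests gave none either, since those tests were not run. Log2 fold changes from counts and FPKM were compared only within the gene FPKM table, with a Pearson correlation of 0.963 across 70 genes, which are not independent replicates.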

Other observations

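The comparisons and tests in this part were chosen after the values were seen, except the counts over other splits of the libraries. Of the 3 pseudoautosomal genes with a tested isoform, 2 had lower summed counts over their isoforms in every knockdown library than in any control. PPP2R3B, summed over its 10 listed isoforms, had 37.04 ± 3.003 CPM in the controls and 22.2 ± 2.21 in the knockdown, and PLCXD1, a phospholipase domain protein, had 98.8 ± 1.62 and 69.8 ± 6.81 CPM over its 11 isoforms (n = 3 each). The exact two-sided permutation p was 0.1 for both, the smallest possible. GTPBP6, between them on the chromosome, had 45.3 ± 3.39 CPM in the controls and 45.6 ± 3.46 in the knockdown (exact permutation p = 1). No single PLCXD1 isoform was called by limma. SLC7A2, a cationic amino acid transporter, had 5.60 ± 0.386 FPKM in the knockdown and 2.76 ± 1.73 in the controls (limma adjusted p = 0.0748), with control 2 at 0.954 FPKM and the other controls at 4.40 and 2.94. SEPTIN5 had 4.27 CPM in control 1 and 21.9 and 22.4 in the other controls, and MRPL49 ran from 21.1 to 84.9 CPM over the 6 libraries.

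The fall of the 5 adjoining transcripts from MT-TF to MT-TL1 was set against 3 technical explanations. Less mitochondrial RNA overall would lower the mRNAs as well, but their median log2 fold change was 0.0786, against -0.52 for the mildest fall of the 5. Scaling of the libraries would leave ratios within a library alone, but against the summed mitochondrial mRNAs of the same library the 5 transcripts changed by -2.28 to -0.564. The median of -1.19 was the change of MT-RNR2 (SE 0.0214), and the SEs of the others ran from 0.0444 to 0.137. A difference in RNA selection before sequencing stays open. The 3 tRNAs of the unit fell with a median of -1.33, and reads on them may come from precursors that hold rRNA, while rRNA of the cytosol was not analysed here. The FPKM of MT-RNR2 was 6.06% of the summed mitochondrial mRNA FPKM in the controls and 2.65% in the knockdown. The fall may thus be in rRNA that such a selection left behind. An effect of the knockdown on the mitochondrial rRNA unit is a hypothesis that these data leave untested.

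The rise of 5 mitochondrial tRNAs (MT-TI, MT-TR, MT-TH, MT-TS2, MT-TL2) could reflect more of the neighbouring mRNAs. The nearest mRNAs on either side did not rise alike: their median log2 fold change was 0.0513, against 0.81 for the mildest of the rises. These medians cannot show whether a small share of reads from longer precursors lay on the tRNAs, because the mRNAs were far higher. In the controls MT-ND4 had 8519 FPKM and the adjoining MT-TH 41.8 FPKM. Control 3 lay toward the knockdown libraries for these tRNAs, which may point to a library difference that it shares with them. In the gene FPKM table control 3 lay at 0.306 on the axis from the other controls (0) to the knockdown mean (1), and control 1 lay at 0.31, a gap well inside its standard error of 0.192, so this explanation stays open, as does an effect of the knockdown.

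PLCXD1 reads were mostly on the isoform ENST00000399012 in control 3 (17.3 FPKM, against 0.263 for ENST00000381657) and mostly on ENST00000381657 in the other 5 libraries (11.3 to 17.9 FPKM). Another isoform, ENST00000448477, had 4.31 to 6.98 FPKM in all 6 libraries. A candidate explanation is that reads were assigned to another overlapping isoform: the sum of ENST00000399012 and ENST00000381657 in control 3 was 0.986 of the mean of the other controls. Calls on single isoforms of such genes could therefore be lost, and no biological explanation was tested.

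The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 4 calls in the gene count table (highest of the other splits 1), 22 in the gene FPKM table (highest other 0) and 16 in the isoform FPKM table (highest other 0), each matched by 1 split, the real one. In the transcript count table the real split gave 0 calls (edgeR, 1 at an unadjusted p under 0.05; DESeq2 called 1 and limma-voom 0), and so did all 10 splits.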
